A study of Homo sapiens with 9 samples.

How the data were processed

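Poly(A) RNA from MCF10A, a non-transformed human mammary epithelial cell line, was sequenced in 9 libraries, per the labels: 3 from cells that carry Cas9 and a control knockout (Control-KO), 3 from APE1-KO cells and 3 from XRCC1-KO cells. RNA was isolated on silica columns and libraries were made with a stranded mRNA kit, per the labels' protocols. Trim Galore, Salmon 1.4.0, edgeR and the genome build hg19 are named in the submitters' processing notes, which give no order or settings. The values used here are 2 tables of the authors' own comparisons, each knockout against Control-KO, with the same 13052 genes in both. Values per library were not analysed here, so the depth of each library is unknown and no value has a replicate SD of its own. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

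Per the file headers, the authors gave each gene a log2 fold change, a mean abundance as log2 CPM (library-scaled counts), an F statistic, a p-value with its false discovery rate, and the −log10 of the p-value. Deposited log2 fold changes are on the scale of knockout over Control-KO, and the deposited mean log2 CPM is a single value per gene, equal in both tables. The F statistic in the authors' deposited tables carries no unit. Adjusting the deposited p-values again with the Benjamini-Hochberg method gave the deposited false discovery rates to within 0.00223. Filters on genes, normalisation and the model formula are not given in the sources used here. Gene coordinates are those of the deposited tables, on hg19. A symbol was given for 12690 genes, and the other 362 genes were used in all counts but not named.

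From these values a standard error was recovered for each gene as the absolute log2 fold change divided by the square root of F. Where F was under 0.01 (830 genes in the XRCC1-KO table and 1485 in the APE1-KO table), the standard error of the other comparison was taken. The standard errors of both comparisons lay within 5% of each other in 97.4% of 10832 genes. The denominator degrees of freedom, solved from F and p, had a median of 15.2, which is also the value used for genes with F under 3. Printed 95% intervals use these standard errors and Student's t quantiles. The response of XRCC1-KO was compared with that of APE1-KO by the difference of the 2 log2 fold changes, which does not contain the control libraries. Its standard error was taken with no covariance between the comparisons, which is conservative because they share their controls, and p-values were adjusted over 13051 genes with the Benjamini-Hochberg method. One gene had no recoverable standard error.

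Before the data were examined, 31 gene lists were fixed from the series title, the cell line and the targeted genes, with 660 entries, of which 576 were measured. The lists cover base excision repair, interferon and nucleic acid sensing, NF-kB and secretory factors, senescence, p53, the cell cycle, telomeres, recombination, stress pathways, metabolism, epithelial states, antigen presentation, matrix, mitochondrial and ribosomal genes, and markers of 4 other cell types. The 29 lists with at least 3 measured members were tested with cameraPR from limma 3.58.1 in R 4.3.3, on signed z values from the deposited p-values, against all other genes. The inter-gene correlation was preset at 0.01, the tests were two-sided, and adjustment ran over the 29 lists of a comparison. That correlation could not be estimated without values per library, so a preset of 0.05 stands in for it, and the report gives that adjusted p where it ends a call. Where the genes of a list vary together by more than the preset, its p-value is too small. List medians have 95% intervals from 10000 resamples of the members, which treat genes as independent. Another 8 groups, chosen after the data were seen, were tested in the same way and adjusted over those 8. Counts of members past adjusted p 0.05 are given over all genes and adjusted over the list alone.

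The naming rule, fixed before the data were examined, takes the targeted genes, genes past adjusted p 0.05 with a mean log2 CPM of at least 1, and all members of a list with 2 or fewer measured. For genes past the threshold it takes the 10 largest rises and falls per comparison, up to 4 members per list, the 5 largest differences per direction between the knockouts, and the 5 largest per direction of those called in both. It leaves out names that are only clone or locus identifiers. Because only APEX1 passed the threshold, further genes were chosen after their values were seen: those with the smallest p-values and a mean log2 CPM of at least 1, and for each list the members with the smallest p-values, whatever their abundance. A few genes, among them LMNB1, NFKBIA and NEIL1, were named for their known roles, also after their values were seen.

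GC content and transcript length came from GENCODE release 29 transcripts, joined by Ensembl identifier, with the longest transcript per gene; 12838 genes (98.4%) had both. No coordinates were taken from that annotation. The trend of log2 fold change with both properties was fitted as cubic terms on nuclear genes and subtracted. Chance values for comparisons with shared controls came from 100 simulated sets of unchanged groups, with the recovered standard errors as modelled and scaled to the spread of the APE1-KO z values. Alternatives tried were stricter thresholds, Bonferroni adjustment, an abundance filter, centring, other presets of the correlation, log2 fold changes or ranks in place of z, removal of the trend, and standard errors scaled to the observed spread. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

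The gene and list tests were tested on simulated data with 11317 genes of mean log2 CPM of at least 1, the recovered standard errors and 200 changed genes. For the simulated XRCC1-KO comparison, 48% of genes changed by 0.5 on the log2 scale were recovered, 96% of those changed by 1, 98% by 1.5 and 98% by 2. For the simulated difference between knockouts the shares were 28%, 88%, 92% and 94%. These shares depend on the 200 changed genes, since the Benjamini-Hochberg threshold loosens as more genes pass. Of the 11087 unchanged genes, 7 were called in the simulated XRCC1-KO comparison. A simulated list of 30 genes raised by 0.2 was found in the simulated XRCC1-KO comparison, with a cameraPR adjusted p of 5.0e-07. The simulated genes varied independently, so this does not check the preset correlation.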

Results

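The transcriptomes of MCF10A cells targeted with Cas9 at the gene for APE1 or XRCC1 were compared with those of Cas9-expressing control cells. APE1, encoded by APEX1, is the endonuclease that cuts DNA at abasic sites in base excision repair. XRCC1 is the scaffold protein that brings ligase and end-processing enzymes to single-strand breaks. The series title names telomeric chromatin leakage, inflammatory signalling and senescence in XRCC1-deficient cells, so the comparisons ask how transcripts of those programmes differ in each knockout. There were 3 libraries in each of the Control-KO, APE1-KO and XRCC1-KO groups. The authors' deposited tables hold 13052 genes with mean log2 CPM from -2.66 to 13.3, of which 11317 had a mean of at least 1.

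The targeted gene was lower in APE1-KO cells and not in XRCC1-KO cells. APEX1 (ENSG00000100823.7, hg19 chromosome 14, 20923350 to 20925927, plus strand) had a log2 fold change of -1.5 in the authors' deposited APE1-KO table (95% interval -1.67 to -1.33, F test p = 5.5e-12, adjusted p = 7.17e-08). Its transcript level was thus 35.4% of that in Control-KO (interval 31.4% to 39.8%). In the deposited XRCC1-KO table APEX1 stood at 0.02 (adjusted p = 0.954). XRCC1 (ENSG00000073050.7, hg19 chromosome 19, 44047192 to 44084625, minus strand) had a log2 fold change of 0.14 in the authors' deposited XRCC1-KO table (interval -0.10 to 0.37, p = 0.235, adjusted p = 0.779). The same gene stood at 0.01 in the authors' deposited APE1-KO table (p = 0.954). A Cas9-induced frameshift need not lower the transcript, so the level of XRCC1 mRNA checks nothing about the XRCC1-KO label, and every direction given for the libraries labelled XRCC1-KO rests on that label.

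**Figure D1:**
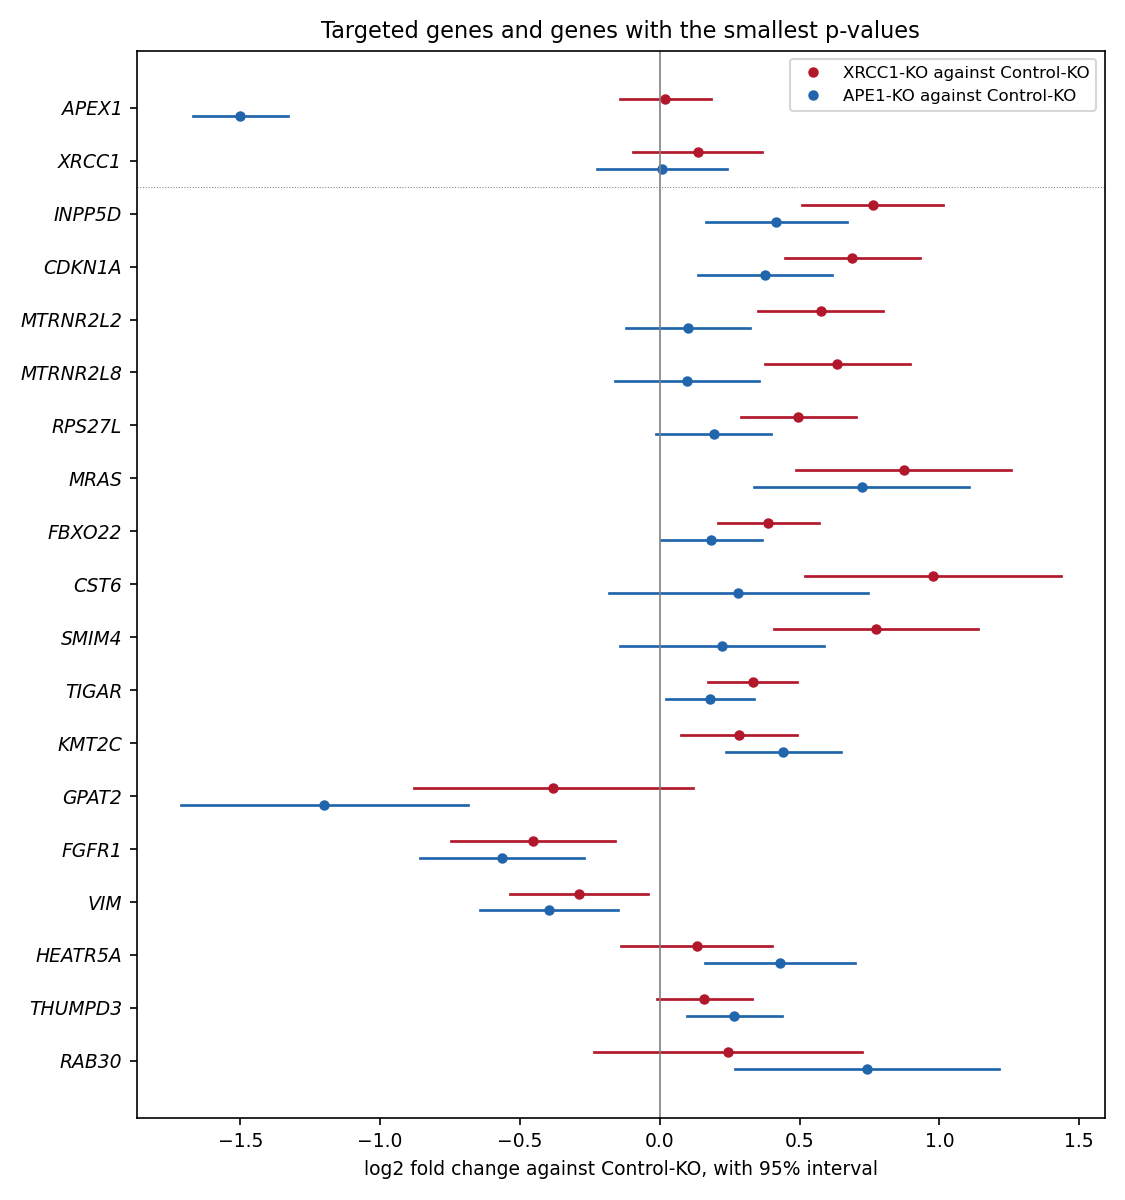
Log2 fold change against Control-KO in the authors' deposited tables (x axis) for the targeted genes APEX1 and XRCC1 and, below the dotted line, the genes of mean log2 CPM of at least 1 with the smallest p-values in XRCC1-KO and then in APE1-KO. Points are the deposited values and lines the recovered 95% intervals; APEX1 in APE1-KO, at -1.5, is the only one past adjusted p 0.05.

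In the libraries labelled XRCC1-KO, genes activated by p53 were higher than in control cells and genes of mitosis were lower. The 28 p53 target genes had a median log2 fold change of 0.25 (interval 0.12 to 0.29), or 1.19-fold, and 26 of them lay above 0 (cameraPR adjusted p = 3.3e-12). The 32 genes of mitosis and G2/M had a median of -0.17 (interval -0.20 to -0.15), or 0.887-fold, and all 32 lay below 0 (cameraPR adjusted p = 2.8e-11). All 13 protein genes of mitochondrial DNA lay above 0, with a median of 0.42 or 1.34-fold, as did all 30 genes of cytosolic ribosomal proteins, with a median of 0.15 or 1.11-fold. No single gene passed adjusted p 0.05 in the authors' deposited XRCC1-KO table, so these are shifts of groups.

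CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, had the smallest p-value among the p53 targets, at 0.69 (1.61-fold, interval 0.45 to 0.93, p = 1.9e-05) in the authors' deposited XRCC1-KO table, with an adjusted p of 0.123. The same table gave 0.33 for TIGAR, a regulator of glycolytic flux, 0.70 for the autophagy and cell death factor TP53INP1, and 0.82 for the secreted cytokine GDF15. Over all genes no member passed, while 10 of the 28 were higher when adjusted over the list alone, and 13 had an unadjusted p under 0.05, all upward. In a test chosen after the data were seen and adjusted over 8 groups, the list kept its call without CDKN1A (cameraPR adjusted p = 1.9e-11, median 0.23 over 27 genes).

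Among mitotic genes, KIF20A, a kinesin of cytokinesis, stood at -0.30, DLGAP5, a spindle protein, at -0.30, NEK2, a centrosomal kinase, at -0.30, and HMMR, a spindle-associated receptor, at -0.20 in the authors' deposited XRCC1-KO table. KIF20A and DLGAP5 were lower when adjusted over the list alone, none passed over all genes, and 9 of the 32 had an unadjusted p under 0.05. The 34 measured genes of DNA replication and G1/S had a median of 0.00 (interval -0.05 to 0.04, cameraPR adjusted p = 0.779). In the list of senescence-related kinase inhibitors and lysosomal markers, CDKN1A was the member that passed adjusted over the list alone, and the 11 measured genes did not shift (median -0.03, cameraPR adjusted p = 0.742). The 14 lamina and chromatin genes reported to be lost in senescence were lower, with a median of -0.10 (cameraPR adjusted p = 0.0143, and 0.0672 with the correlation preset at 0.05). LMNB2, a B-type lamin, stood at -0.22 and LMNB1 at -0.15 (p = 0.0562) in the authors' deposited XRCC1-KO table, and no member passed over all genes or adjusted over the list alone.

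The mitochondrially encoded genes shifted upward in the libraries labelled XRCC1-KO with a cameraPR adjusted p of 5.7e-11. Genes of this list, like those of ribosomal proteins, may vary together between libraries by more than any preset correlation. Their list p-values may then be far too small. ND6, a complex I subunit and the protein gene on the light strand, stood at 0.83 in the authors' deposited XRCC1-KO table, with COX3 at 0.45, ND3 at 0.38 and COX2 at 0.48. Adjusted over the list alone, 5 of the 13 were higher, and none passed over all genes. Cytosolic ribosomal protein genes had a cameraPR adjusted p of 1.2e-08; RPLP1, at 0.28, was the 1 member of 30 with an unadjusted p under 0.05, and none passed over all genes or adjusted over the list alone. With log2 fold changes in place of z values the ribosomal list missed the threshold (cameraPR adjusted p = 0.204). Keratinocyte differentiation genes were higher, with a median of 0.43 over 24 measured members (cameraPR adjusted p = 3.5e-05). Involucrin (IVL), a precursor of the cornified envelope, stood at 0.52, keratin 16 (KRT16) at 0.39 and the antimicrobial protein S100A7 at 1.34 in the deposited XRCC1-KO table, and none passed over all genes or adjusted over the list alone.

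**Figure D2:**
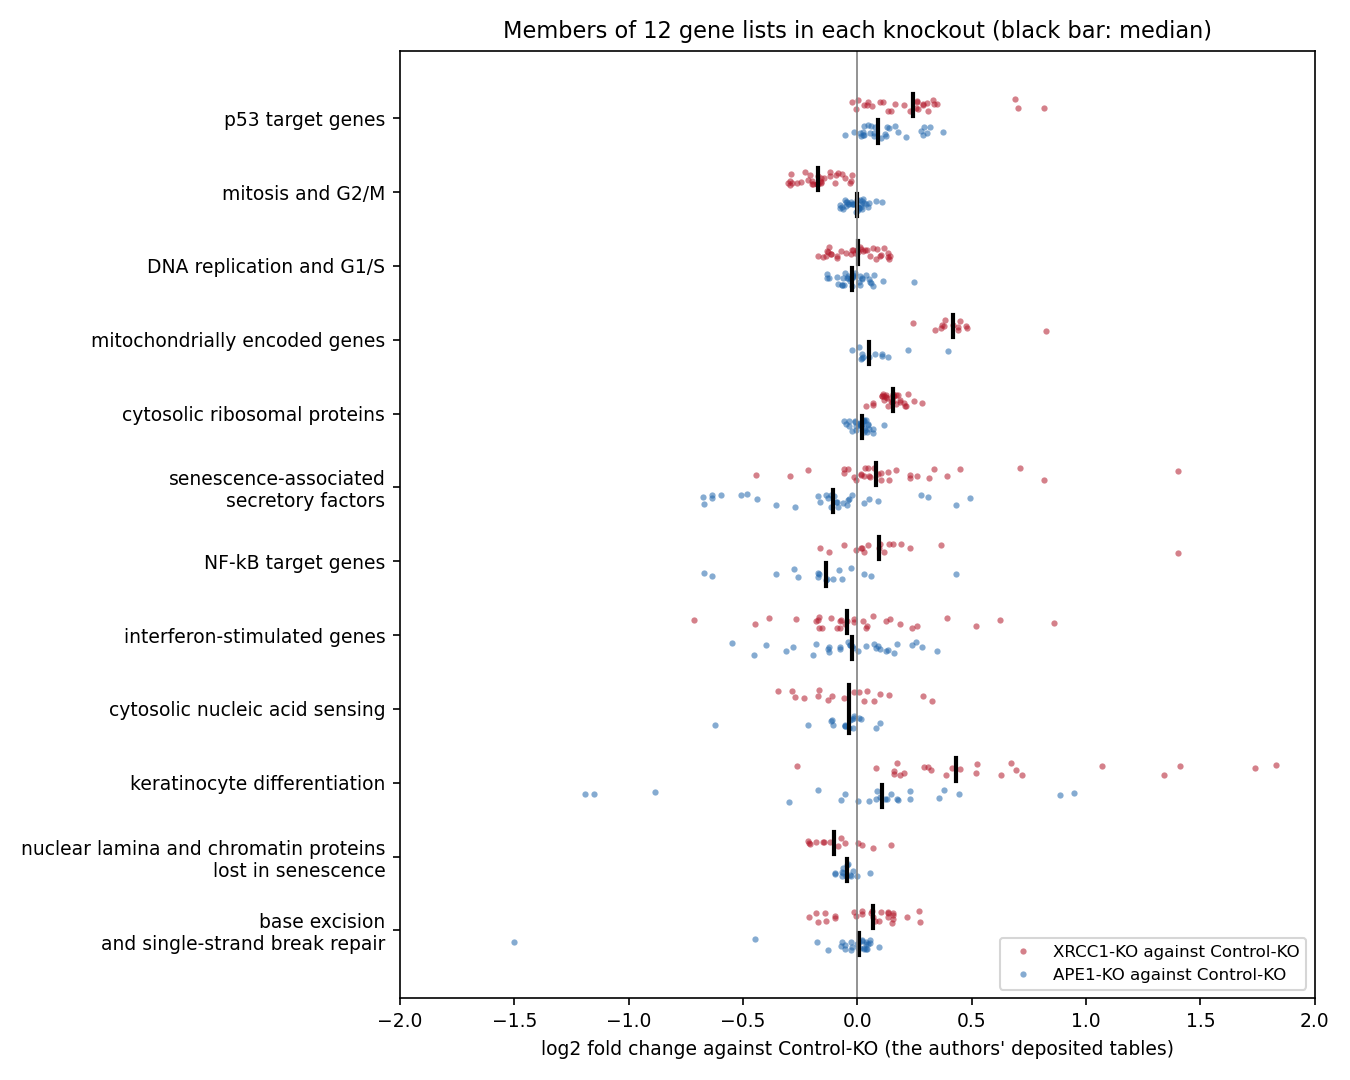
Log2 fold change against Control-KO of each measured member (points) of 12 gene lists, with XRCC1-KO in red and APE1-KO in blue, from the authors' deposited tables; black bars are medians. In XRCC1-KO all 32 mitotic genes lie below 0 and all 13 mitochondrially encoded genes above it; NF-kB targets and secretory factors have medians above 0 in XRCC1-KO and below 0 in APE1-KO.

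Interferon-stimulated and nucleic acid sensing genes did not shift in the libraries labelled XRCC1-KO, while the inflammatory lists had small medians above 0. The 31 measured interferon-stimulated genes had a median of -0.05 (interval -0.09 to 0.04, cameraPR adjusted p = 0.904), with members on both sides: OAS1, an antiviral oligoadenylate synthetase, stood at -0.71 and TRIM22, an antiviral ubiquitin ligase, at 0.52 in the authors' deposited XRCC1-KO table. At an unadjusted p under 0.05, 4 members of this list were higher and 1 lower. The 18 genes of cytosolic nucleic acid sensing had a median of -0.04 (cameraPR adjusted p = 0.321). The 17 NF-kB targets had a median of 0.09 (interval 0.02 to 0.16, 13 above 0), and their list did not pass (cameraPR adjusted p = 0.161). Secretory factors of senescent cells passed, with a median of 0.08 over 32 genes (cameraPR adjusted p = 0.0361), but not with the correlation preset at 0.05 (adjusted p = 0.20). GDF15 was the member of that list that passed adjusted over the list alone; the chemokine CXCL3 stood at 1.4, LIF at 0.71 and IL1A at 0.31 in the deposited XRCC1-KO table.

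A further 3 lists passed in the libraries labelled XRCC1-KO and lost the call with the correlation preset at 0.05: NRF2 targets (median 0.08, cameraPR adjusted p = 0.0361, then 0.174), cholesterol synthesis (0.07, 0.0361, then 0.174) and homologous recombination with Fanconi anaemia genes (-0.09, 0.0363, then 0.196). No member of these 3 lists passed over all genes or adjusted over the list alone; OSGIN1, a stress-induced growth inhibitor, stood at 0.61 and the sterol enzyme MVD at 0.21 in the deposited XRCC1-KO table. Unfolded protein response and ATF4 targets (median 0.10, cameraPR adjusted p = 0.0629), mesenchymal transition genes (0.11, 0.115), base excision repair (0.07, 0.164), class I antigen presentation (0.07, 0.164), luminal markers (0.11, 0.20) and immediate early genes (0.07, 0.21) did not pass. Nor did epithelial adhesion (-0.05, cameraPR adjusted p = 0.213), basal markers (0.03, 0.562), matrix genes (0.07, 0.653), hypoxia and glycolysis (0.01, 0.885) or shelterin and telomere genes (0.03, 0.779). TINF2, a shelterin component, stood at 0.28 (p = 0.0113) in the authors' deposited XRCC1-KO table. Markers of neurons (0.21 over 3 genes, cameraPR adjusted p = 0.463), leukocytes (0.15 over 6, 0.625; mean -0.14) and fibroblasts (0.06 over 4, 0.904) did not shift. Lists with fewer measured members were not tested: HLA-DMA stood at 0.88 and CIITA at 0.45 among class II genes, and KDR, an endothelial receptor, at -0.45 in the deposited XRCC1-KO table.

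Gene by gene, 778 of 13052 genes had an unadjusted p under 0.05 in the authors' deposited XRCC1-KO table, 425 higher and 353 lower, where evenly spread p-values would give 652.6. Among genes with mean log2 CPM of at least 1, the robust SD of the XRCC1-KO z values was 1.22. With the trend of GC content and transcript length removed it was 0.972, so the excess over evenly spread p-values may come from that trend. For APE1-KO the robust SD was 0.674, and 0.645 with the trend removed. The XRCC1-KO values thus stayed wider than those of APE1-KO, and the trend does not account for that difference as a whole. The smallest p-value belonged to INPP5D, the inositol phosphatase SHIP1 (hg19 chromosome 2, 233924677 to 234116549), at 0.76 or 1.69-fold (interval 0.51 to 1.01, p = 1.03e-05, adjusted p = 0.123) in the authors' deposited table. After INPP5D and CDKN1A came MTRNR2L2 at 0.58 and MTRNR2L8 at 0.64, nuclear copies of the mitochondrial 16S rRNA gene that can share reads with it, and RPS27L, a ribosomal protein paralog, at 0.50. The same deposited table gave 0.87 for the small GTPase MRAS, 0.39 for the ubiquitin ligase subunit FBXO22, 0.98 for the protease inhibitor CST6 and 0.77 for SMIM4. Lower values there belonged to the collagen gene COL22A1 at -1.10, the Mediator kinase-module subunit MED12 at -0.51, the adhesion molecule NECTIN1 at -0.26 and the channel subunit LRRC8B at -0.62. The recovered standard error had a median of 0.112 over genes with mean log2 CPM of at least 1.

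Fold changes in XRCC1-KO also followed transcript length and GC content across genes. With genes in 10 bins by transcript length, the median log2 fold change was 0.13 in the bin of shortest transcripts and -0.09 in the bin of longest; for APE1-KO the same bins stood at 0.00 and 0.03. Across 11175 nuclear genes, which are not independent replicates, Spearman's rho of the XRCC1-KO log2 fold change was -0.419 with transcript length and 0.333 with GC content, against 0.102 and -0.201 for APE1-KO. With that trend removed, a step chosen after the data were seen, p53 targets, mitosis, mitochondrially encoded, ribosomal, keratinocyte and lamina lists still passed. The ribosomal median dropped from 0.15 to 0.09, the keratinocyte median from 0.43 to 0.30 and the mitochondrial median from 0.42 to 0.29. The NRF2 median dropped from 0.08 to 0.02, that of cholesterol synthesis from 0.07 to 0.05 and that of recombination from -0.09 to -0.03, and these lists did not pass (cameraPR adjusted p = 0.217, 0.0765 and 0.232). The secretory list did not pass either (0.217), but its median stayed at 0.08.

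**Figure D3:**
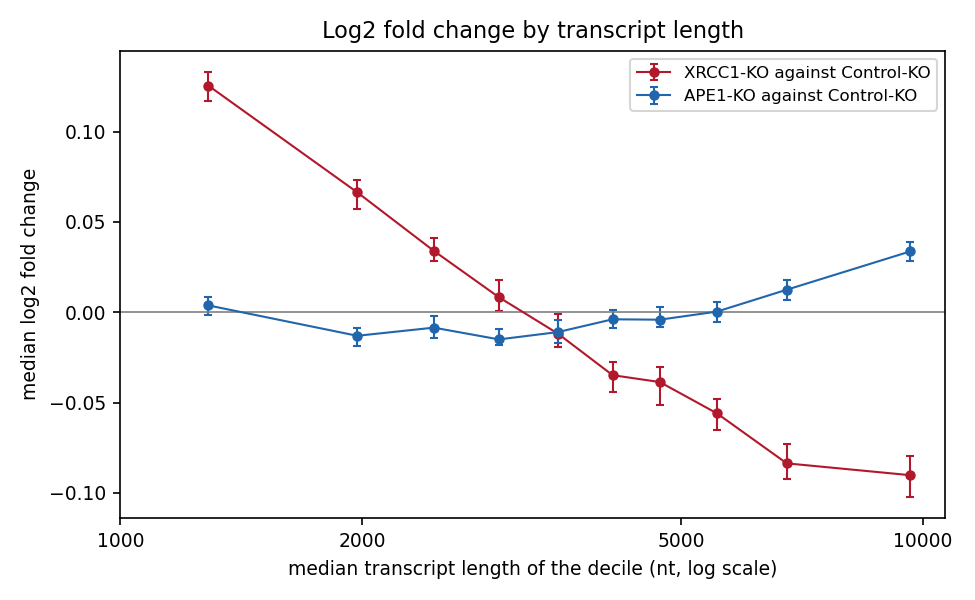
Median log2 fold change against Control-KO (y axis) in 10 bins of nuclear genes by transcript length in nt (x axis, log scale), with 95% bootstrap intervals as bars; genes have a mean log2 CPM of at least 1. XRCC1-KO falls from 0.13 in the bin of shortest transcripts to -0.09 in that of longest, while APE1-KO stays between -0.02 and 0.03.

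In APE1-KO cells APEX1 was the 1 gene of 13052 past adjusted p 0.05 in the authors' deposited table, and it fell. Beyond it, p53 targets were higher by a smaller amount, with a median of 0.09 or 1.07-fold over 28 genes (interval 0.05 to 0.15, cameraPR adjusted p = 1.4e-07). NF-kB targets were lower, with a median of -0.14 over 17 genes, 14 of them below 0 (cameraPR adjusted p = 9.8e-05). Secretory factors of senescent cells were also lower, with a median of -0.11 over 32 genes (cameraPR adjusted p = 3.9e-04). Genes of cholesterol synthesis were higher, at a median of 0.06, with 20 of 21 above 0 (cameraPR adjusted p = 5.5e-04). Their median in XRCC1-KO was 0.07, and the difference between the knockouts was 0.01 (cameraPR adjusted p = 0.949). A part from the shared control libraries thus stays open for this list.

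CXCL1 and CXCL8, neutrophil-attracting chemokines held by both the NF-kB and the secretory list, stood at -0.63 (p = 0.0118) and -0.67 (p = 0.0256) in the authors' deposited APE1-KO table. The NF-kB subunit RELB stood at -0.28, the inhibitor NFKBIA at -0.13 and the metalloproteinase MMP9 at -0.51 in that table. Among p53 targets, CDKN1A stood at 0.38 (p = 0.00453), the RNA-binding protein gene ZMAT3 at 0.32 and TIGAR at 0.18 in the authors' deposited APE1-KO table. The sterol oxidase gene MSMO1 stood at 0.18 there. No member of these 4 lists passed over all genes or adjusted over the list alone. With log2 fold changes in place of z values, all 4 lost the call (cameraPR adjusted p = 0.24 for p53 targets, 0.24 for NF-kB, 0.109 for secretory factors and 0.983 for cholesterol synthesis). Neuronal markers passed on 3 measured genes (median 0.68, cameraPR adjusted p = 7.8e-04), of which the synaptic vesicle gene SYT1, at 1.21, passed adjusted over the list alone; TUBB3 stood at 0.10 and MAP2 at 0.68 in the deposited APE1-KO table.

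The other lists did not pass in APE1-KO with the settings fixed at the start, though keratinocyte genes passed with only genes of mean log2 CPM of at least 1 (cameraPR adjusted p = 0.0439) and lamina and chromatin genes with ranks (0.0228). In the list of kinase inhibitors and lysosomal markers (median 0.01, cameraPR adjusted p = 0.826), CDKN1A passed adjusted over the list alone. Interferon-stimulated genes had a median of -0.02 (cameraPR adjusted p = 0.869), nucleic acid sensing -0.03 (0.149), mitosis 0.00 (0.826) and DNA replication -0.02 (0.639). Lamina and chromatin genes had a median of -0.05 (cameraPR adjusted p = 0.0709), mitochondrially encoded genes 0.05 (0.0994), class I antigen presentation -0.04 (0.134) and keratinocyte genes 0.11 (0.154). Base excision repair had a median of 0.01 and a mean of -0.08 (cameraPR adjusted p = 0.149); within it APEX1 fell over all genes and adjusted over the list alone, and the glycosylase NEIL1 stood at -0.45 (p = 0.0695) in the authors' deposited APE1-KO table. TERF1, a shelterin protein that binds telomeric DNA, stood at 0.26 (p = 0.00774) in the authors' deposited APE1-KO table, while its list had a median of -0.02 (cameraPR adjusted p = 0.845). The remaining lists had cameraPR adjusted p from 0.388 for matrix genes to 0.964 for leukocyte markers. Of the lists too small to test, HLA-DMA stood at 1.06, CIITA at 0.56 and KDR at -0.42 in the deposited APE1-KO table.

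Only 189 genes had an unadjusted p under 0.05 in the authors' deposited APE1-KO table, 101 higher and 88 lower, against 652.6 for evenly spread p-values. After APEX1, among genes with mean log2 CPM of at least 1, the smallest p-values belonged to the histone methyltransferase KMT2C at 0.44, GPAT2 at -1.20, the growth factor receptor FGFR1 at -0.56, MRAS at 0.72, INPP5D at 0.42 and the intermediate filament gene VIM at -0.40. All of these had an adjusted p of 1 in the deposited APE1-KO table.

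**Figure D4:**
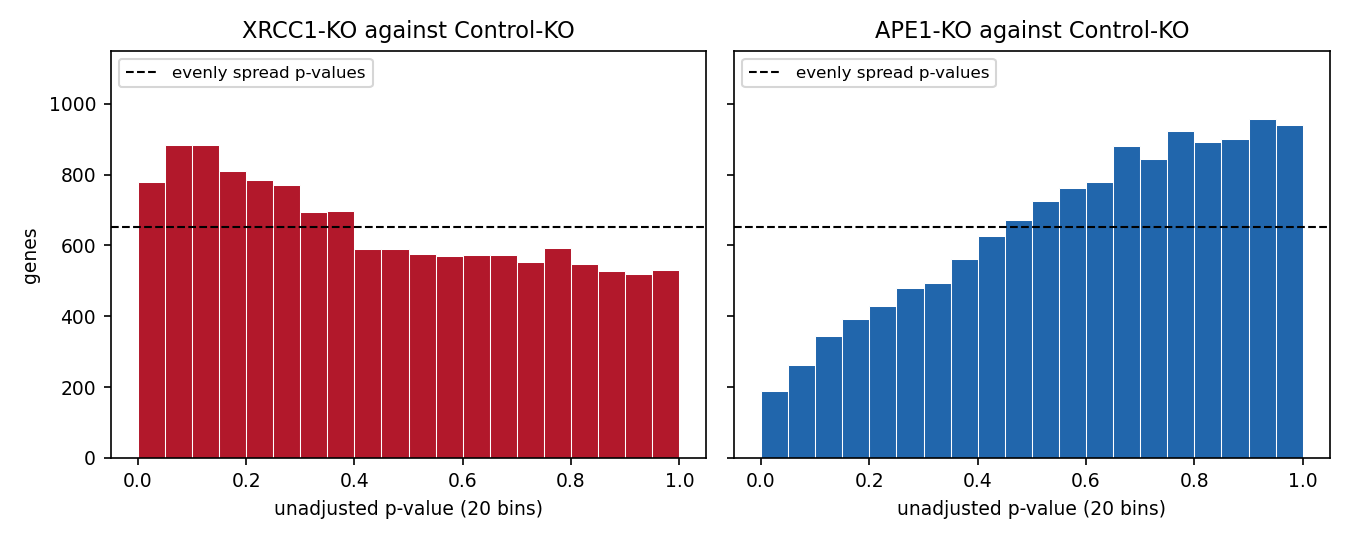
Number of genes (y axis) in 20 equal bins of the unadjusted p-value (x axis) in the authors' deposited XRCC1-KO and APE1-KO tables, with a dashed line at the 652.6 genes that evenly spread p-values would put in each bin. In the lowest bin XRCC1-KO has 778 genes and APE1-KO 189.

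No gene passed adjusted p 0.05 in both knockouts, as the XRCC1-KO table has none. At an unadjusted p under 0.05, 35 genes were above 0 in both deposited tables, 19 below 0 in both and 1 on opposite sides. Independent lists of these sizes would share 3.29, 2.38 and 5.60 genes. Unchanged groups simulated against shared controls gave means of 71.1, 71.5 and 1.14 with the modelled spread, and 6.16, 5.49 and 0.01 with the spread scaled to the APE1-KO z values. The observed 35 and 19 lie between these, so how much of the overlap comes from the shared controls was left undecided. Neither simulation matched both tables, as the modelled spread gave 655 genes under p 0.05 in APE1-KO, where 189 were observed, and the scaled spread 82.7 in XRCC1-KO, where 778 were. The correlation across 11317 genes of the z values was 0.305, against 0.50 in both simulations, with a covariance of 0.244 against 0.50 and 0.24. For log2 fold changes the covariance was 0.00805, against 0.0137 and 0.00654 simulated. Chosen after their values were seen, the genes of mean log2 CPM of at least 1 with the largest values on the same side were MRAS, A2ML1, C3orf62, H2AC18 and SCEL upward and COL22A1, FGFR1, IL15RA, VIM and SH3RF3 downward. MRAS stood at 0.87 and 0.72 and VIM at -0.29 and -0.40 in the deposited XRCC1-KO and APE1-KO tables, and HAUS5 was the gene on opposite sides, at 0.25 and -0.26.

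The knockouts differed most clearly in inflammatory, mitotic and mitochondrial genes. Secretory factors were higher in XRCC1-KO than in APE1-KO by a median of 0.25 on the log2 scale (27 of 32 above 0, cameraPR adjusted p = 8.7e-07), as were NF-kB targets, by 0.27 (16 of 17, 8.8e-06). Mitotic genes were lower by a median of -0.17 (30 of 32 below 0, cameraPR adjusted p = 3.9e-10). Mitochondrially encoded genes were higher by 0.34 (13 of 13, cameraPR adjusted p = 3.0e-07), ribosomal protein genes by 0.14 (30 of 30, 1.6e-06) and p53 targets by 0.10 (20 of 28, 3.6e-04). With the trend of GC content and transcript length removed, the ribosomal difference dropped to 0.08 (cameraPR adjusted p = 0.00396) and the mitochondrial one to 0.26 (5.6e-05). The control libraries cancel out of all these differences.

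Gene by gene, APEX1 was the 1 gene of 13051 whose response differed past the threshold, by 1.52 (interval 1.28 to 1.76, test of the difference on recovered standard errors, adjusted p = 7.1e-06). With APEX1, 96 genes had an unadjusted p under 0.05, fewer than evenly spread p-values would give. The standard error leaves out the covariance from the shared controls, which makes the test conservative, so neither count shows that few genes differ. The difference of deposited log2 fold changes was 0.37 for AREG, an EGF receptor ligand, 0.65 for CXCL1, -0.25 for KIF20A, -0.26 for DLGAP5, 0.43 for COX3 and 0.31 for CDKN1A. None of these 6 passed over all genes or adjusted over its list alone. With log2 fold changes in place of z values, the p53 and ribosomal lists no longer differed (cameraPR adjusted p = 0.477 and 0.378).

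A further 5 lists were higher in XRCC1-KO than in APE1-KO: base excision repair (median 0.10, cameraPR adjusted p = 0.00438), class I antigen presentation (0.14, 0.00639), keratinocyte differentiation (0.26, 0.00639), unfolded protein response and ATF4 targets (0.11, 0.0179) and mesenchymal transition (0.12, 0.0487). All 5 lost the call with the correlation preset at 0.05 (cameraPR adjusted p = 0.0555, 0.0555, 0.0618, 0.0939 and 0.173). With the trend of GC content and transcript length removed, the first 4 lost it as well (cameraPR adjusted p = 0.0616, 0.0607, 0.0907 and 0.22), their medians dropping to 0.04, 0.07, 0.14 and 0.09, while mesenchymal transition stayed at 0.12 (0.0262). In a test chosen after the data were seen and adjusted over 8 groups, the 25 base excision repair genes other than APEX1 and XRCC1 did not pass (median 0.10, cameraPR adjusted p = 0.0856). Interferon-stimulated genes (median -0.02), nucleic acid sensing (0.04), DNA replication (0.00) and shelterin genes (-0.02) all had a cameraPR adjusted p of 0.949 for the difference.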

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

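Of the tests in this part, the removal of the trend with GC content and transcript length, the comparison of mitotic with replication genes, the comparison of the covariance with 0.5, and the tests of base excision repair without the targeted genes and of secretory factors without NF-kB targets were chosen only after the main results were seen. The results here stand out because the effect of one knockout against Control-KO differed from that of the other in a test of the difference itself. APEX1 differed by 1.52 on the log2 scale, from its fall in APE1-KO. The lists that differed, by median difference of log2 fold changes (XRCC1-KO minus APE1-KO), were mitosis and G2/M (-0.17), mitochondrially encoded genes (0.34), senescence-associated secretory factors (0.25), cytosolic ribosomal proteins (0.14), NF-kB targets (0.27) and p53 targets (0.10). The same test gave base excision repair (0.10), keratinocyte differentiation (0.26), class I antigen presentation (0.14), unfolded protein response and ATF4 targets (0.11) and mesenchymal transition (0.12). In the same order, these 5 lost the call with the correlation preset at 0.05 (cameraPR adjusted p = 0.0555, 0.0618, 0.0555, 0.0939 and 0.173). Base excision repair also lost it without APEX1 and XRCC1 (cameraPR adjusted p = 0.0856, adjusted over 8 groups), though its median difference stayed at 0.10. Of the 27 secretory factors that are not on the NF-kB list, the median difference was 0.19 (cameraPR adjusted p = 2.3e-05, adjusted over the same 8 groups). The splits of the libraries that would test chance groupings need values per library and were not run.

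The first pattern is the rise of p53 targets with the fall of mitotic genes in XRCC1-KO. The trend with GC content and transcript length does not account for it as a whole: with the trend removed, the p53 median was 0.19 (interval 0.11 to 0.27) against 0.25 before, and the mitotic median -0.16 (interval -0.18 to -0.14) against -0.17. A smaller share of cells in the whole cycle would lower replication genes as well, and the mitotic median lay under the replication median by -0.17 (interval -0.22 to -0.12). That interval resamples genes measured in the same libraries, so it does not measure variation between cultures. The shared control libraries do not account for it as a whole either, since they cancel out of the differences between the knockouts (-0.17 for mitosis, 0.10 for p53 targets); for the part of the p53 rise seen in both knockouts they stay open. Open and untested are a response to the loss of XRCC1, in which p21, encoded by CDKN1A, may lower G2 and M transcripts, and a difference between cell clones or cultures.

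The second pattern is the rise of mitochondrially encoded and ribosomal protein genes in XRCC1-KO, both short transcripts. With the trend removed the ribosomal median was 0.0866 (interval 0.04 to 0.13) against 0.15. The mitochondrial median was 0.29 (interval 0.25 to 0.31) against 0.42. Shares of 0.562 and 0.691 of the medians were kept, under the bound written before this test was run. Both lists still passed the list test. Because the shares fell under the bound, removing the trend cannot decide whether it accounts for part or the whole of each shift. The ribosomal median of 0.15 lay near the 0.13 of all genes in the bin of shortest transcripts. The trend was fitted on nuclear genes, so the mitochondrial genes lay outside the fit. The 13 mitochondrial genes spread no more than their errors allow (Cochran Q, chi-square p = 0.941, and 0.444 with errors scaled to the APE1-KO spread). Cochran Q takes the errors as independent, but all 13 values come from the same libraries, and variation that the genes share lowers Q. The test therefore cannot decide whether one factor acts on all transcripts from mitochondrial DNA, such as more mitochondrial RNA per cell or in the poly(A) fraction. A biological effect of the knockout and a difference in RNA quality or library preparation between the groups both stay open, as neither was tested.

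The third pattern is the crowding of APE1-KO p-values towards 1. Low counts do not account for it: among genes with mean log2 CPM of at least 5 the SD of z was 0.669 (interval 0.65 to 0.689), where 1 would fit the model. The differences between APE1-KO and Control-KO were thus smaller across these genes than the modelled spread implies. Why they were smaller stays open, including whether the libraries of these groups spread less than modelled. The covariance of z between the comparisons was 0.244 (interval 0.235 to 0.257), under the 0.5 of a correct spread, but the narrow APE1-KO z values alone would put it near 0.265, so it decides nothing. No biological explanation was tested, and values per library were not analysed here.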

How the results depend on the processing

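The 4 counts of genes stayed the same under stricter thresholds and the abundance filter. Centring, tried for all of them but the overlap of both knockouts, changed no count either. With the abundance filter the lists shifted in XRCC1-KO went from 10 to 9, losing recombination (cameraPR adjusted p = 0.0557), and the lists that differed from 11 to 12; APE1-KO kept 5, with keratinocyte genes in and the neuronal list, too small to test there, out. With ranks the 3 counts of lists were 9, 6 and 11, the secretory call in XRCC1-KO being lost. Chosen after the data were seen, scaling the standard errors by the robust SD of the APE1-KO z values (0.674) gave 126 genes in XRCC1-KO (77 higher, 49 lower, with 8 p53 targets) in place of 0, and 3 in APE1-KO in place of 1; it assumes that APE1-KO changed few genes and leaves the length trend in. The 10 lists shifted in XRCC1-KO became 5 with the inter-gene correlation preset at 0.05, 6 at 0.02, 4 with log2 fold changes in place of z and 6 with the trend of GC content and transcript length removed, the last and the 0.02 preset also chosen after the data were seen. The 5 lists in APE1-KO became 1 with log2 fold changes in place of z. The 11 lists that differed between the knockouts became 6 at 0.05, 5 with log2 fold changes and 7 with the trend removed, which ended the base excision repair, class I, keratinocyte and unfolded protein response differences. Fewer lists pass at a higher preset because the preset widens the null; for log2 fold changes the cause was not tested. Passing only under an alternative were keratinocyte (abundance filter, 0.0439) and lamina genes (ranks, 0.0228) in APE1-KO and the NRF2 difference (ranks, 0.0372; abundance filter, 0.0409). No list reversed past its threshold. The p53, mitosis, mitochondrial and keratinocyte lists in XRCC1-KO passed under all 6 alternatives, as did the NF-kB, secretory, mitosis and mitochondrial differences. No paired analysis was possible because the deposited comparisons carry no values per library; for the same reason leave-one-out fits, other count models, an estimated correlation and other splits were not run. Depth is unknown. In the simulated XRCC1-KO comparison 48% of changes of 0.5 on the log2 scale were recovered. The changed genes planted there loosened the Benjamini-Hochberg threshold. No gene passed in the deposited XRCC1-KO table, so that share does not carry over to it. In that table INPP5D at 0.76 and CDKN1A at 0.69 had an adjusted p of 0.123, and CST6 at 0.98 had 0.509. Changes of single genes of this size could thus be missed, and smaller ones were mostly out of reach.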

Other observations

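The groups in this part were chosen after the data were seen, and their tests were adjusted over the 8 groups tried. Nuclear-encoded subunits of the respiratory chain and ATP synthase were higher in XRCC1-KO together with the mitochondrially encoded ones: 71 of 75 lay above 0, with a median log2 fold change of 0.18 (cameraPR adjusted p = 9.2e-15), and 0.09 with the trend of GC content and transcript length removed (adjusted p = 5.4e-06). NDUFS6, a complex I subunit, stood at 0.35 and UQCR11, of complex III, at 0.47 in the authors' deposited XRCC1-KO table. The 73 mitochondrial ribosomal proteins had a median of 0.12 (cameraPR adjusted p = 1.1e-08), and 0.04 with the trend removed (adjusted p = 0.0103). In APE1-KO the same groups had medians of 0.02 and 0.00 (cameraPR adjusted p = 0.0641 and 0.642), and both differed between the knockouts (cameraPR adjusted p = 2.0e-10 and 1.9e-07). The median differences were 0.15 and 0.11, and dropped to 0.06 and 0.04 with the trend removed (cameraPR adjusted p = 1.3e-04 and 0.012). The 6 humanin-like MTRNR2L genes had a median of 0.59 in XRCC1-KO (cameraPR adjusted p = 5.1e-11) and 0.07 in APE1-KO. They are near-identical to mitochondrial 16S rRNA, so their values are uncertain and can hold reads from mitochondrial DNA. The 6 values may then largely repeat a single measurement, which the preset correlation of 0.01 does not allow for. Their list p-value may be far too small and is no measure of support.

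Histone genes passed the list test upward in both knockouts, with medians of 0.26 in XRCC1-KO (cameraPR adjusted p = 0.00395) and 0.19 in APE1-KO (0.00201) over 18 genes. Both median intervals included 0 (-0.09 to 0.55 and -0.01 to 0.30), with 12 and 13 of the 18 genes above 0. H2BC4 stood at 1.09 and 0.79 and H2AC18 at 0.79 and 0.50 in the authors' deposited XRCC1-KO and APE1-KO tables. With the trend removed the XRCC1-KO call ended (cameraPR adjusted p = 0.119, median 0.09), and both comparisons use the same controls. Near-identical histone copies share reads, and a poly(A) library holds only the polyadenylated part of their transcripts. The 379 zinc finger genes named ZNF, a large family of long transcripts, did not pass the list test in XRCC1-KO (median -0.03, cameraPR adjusted p = 0.329). Their median interval lay under 0 (-0.04 to -0.01), with 219 genes below 0 and 160 above. With the trend removed the median was -0.0014 (interval -0.02 to 0.01).

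A hypothesis was that genes spanning more of the genome are lower in XRCC1-KO, as unrepaired single-strand breaks could slow transcription along long genes. With GC content and transcript length in the model, the slope of log2 fold change on log2 genomic width was -0.0123 per doubling (chromosome bootstrap interval -0.0147 to -0.0100) over 11173 genes, and 0.00108 (interval -0.000468 to 0.00267) in APE1-KO. The intervals resample chromosomes measured in the same libraries, so they do not measure variation between libraries. The slope on transcript length in XRCC1-KO was larger per doubling, at -0.0482. Taken alone, Spearman's rho with the XRCC1-KO log2 fold change was -0.377 for genomic width and -0.419 for transcript length. Genomic width may thus add to a trend that RNA quality or library preparation could also give. The difference between the knockouts in the slope on genomic width was not tested.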
